A study of Homo sapiens with 6 samples.

How the data were processed

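Total RNA from 6 samples of C4-2 cells, 3 expressing wild-type PARP1 and 3 expressing PARP1 K607A over a knockdown of endogenous PARP1, had been extracted with a column kit and made into stranded total RNA libraries by the study's authors. The deposited table gives raw read counts per gene, whole numbers that had not been normalized, and the gene's exonic coordinates and length in the layout of featureCounts. The submitters' processing notes name HISAT2 2.1.0 and featureCounts 1.6.1, the builds GRCh38 and hg38, and edgeR and limma with no role; the annotation release and the settings for strand and for reads that map to several places are not given in the sources used here. How such reads were counted affects genes with near-identical copies. Of the gene rows, 59384 were used, and 1 row that breaks off before its counts, that of ANK2, was left out. All 6 samples were used, with their group and replicate number taken from their titles.

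Counts were compared between K607A and WT with the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), two-sided, with group as the only term, TMM normalization, the filterByExpr filter at its defaults and a Benjamini-Hochberg adjusted p under 0.05. Positive log2 fold changes mean higher in K607A. The filter left 15603 genes, and the common biological coefficient of variation was 6.97%. Levels are CPM with TMM library sizes, given as mean ± SD over the 3 libraries of a group, and the standard error of a log2 fold change was derived from the F statistic. The standard error of a list's mean log2 fold change is instead taken over its member genes. It measures the spread between genes, which are not independent replicates, and not the spread between libraries. The libraries held 18796167 to 19048628 counts. A ratio of summed counts has an exact Clopper-Pearson 95% interval, and such intervals cover counting error only. The replicates of a group were compared pairwise by chi-square over the 15603 genes, and every pair differed by more than sampling noise, so all were kept as separate samples.

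The tests, the alternatives, the rule for naming genes and 31 gene lists were fixed before the data were examined. PARP1 and EZH2 are always named. Of the genes past the threshold that were protein-coding, had a mean of at least 1 CPM and had all 3 samples of one group above all 3 of the other, the 12 with the largest increase and the 12 with the largest decrease are named, out of 284 such genes. From each list the rule picks up to 4 tested members with the smallest p. The text prints only some of these, chosen for length after the results were seen, and other genes are said to have been singled out afterwards. Lists were tested with camera (limma 3.58.1), two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 tested members. Camera with a correlation estimated for each list and fry, which tests whether a list's genes move on balance one way, were run beside it. Each list's count of members past the threshold is given over all genes and adjusted over the list alone. A range over 5 other fits is that of the count over all genes with DESeq2, limma-voom, the replicate block, the GC correction and the fit without both libraries at the ends of the GC trend. Of the genes in the lists, 6 were not found under any of their names. Some lists share members, so a gene can count in several. NDRG1 is in the androgen receptor and hypoxia lists and CLSPN in the E2F and end joining lists. ATF3 is in the immediate early and unfolded protein response lists.

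The lists cover E2F targets, mitosis, replication-dependent histones, homologous recombination and Fanconi anaemia, non-homologous end joining and checkpoints, the PARP family with base excision repair, NAD metabolism, Polycomb components, genes reported as silenced by EZH2, androgen receptor targets, epithelial and mesenchymal genes, markers of basal, endothelial, neuroendocrine, fibroblast and leukocyte cells, interferon, NF-kB, hypoxia and glycolysis, the unfolded protein response with ATF4 targets, immediate early genes, heat shock, MYC targets with ribosome biogenesis, cytoplasmic ribosomal proteins, cholesterol and fatty acid synthesis, p53 targets, nuclear-encoded respiratory chain genes, mitochondrially encoded mRNAs, nuclear-retained lncRNAs and small structured RNAs.

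Alternatives fixed beforehand were DESeq2 size factors in the same test, a filter at 1 CPM in 3 samples, no filter beyond 1 count, the replicate number as a block, removal of mitochondrial, histone and structured RNA genes, DESeq2 1.42.0, limma-voom, an absolute log2 fold change of at least 1, an adjusted p under 0.01, an estimated correlation in camera, and leaving out each library in turn. Chosen after seeing the data were a correction that removes each library's lowess trend (span 0.3) of log2 CPM on GC content, leaving out both libraries at the ends of that trend, the sum of SMN1 and SMN2, and leaving out genes with transcripts on patches or alternate loci. GC content, biotypes and those transcripts came from GENCODE release 29, which gave a GC value for 89.8% of tested genes and a biotype for 91.3%.

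The procedure was tested on simulated counts of 15418 genes in 3 against 3 samples, with 200 genes changed in each of 5 sets. Of 50 genes changed by each fold, it recovered 41.2% at 1.3-fold, 80.8% at 1.5-fold, 95.2% at 2-fold and 100% at 4-fold, and 9.25% of its calls were unchanged genes against the nominal 5%. A simulated list of 50 genes shifted 1.15-fold was called with the preset and with the estimated correlation. With the preset correlation 0 of 30 unshifted lists were called. Genes were drawn independently of each other, so neither result covers lists whose genes vary together.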

Results

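Gene expression was measured by total RNA sequencing in C4-2 cells, a castration-resistant human prostate cancer line derived from LNCaP. Endogenous PARP1 had been knocked down in all samples, and the cells stably expressed either wild-type PARP1 (WT, n = 3) or PARP1 K607A, in which alanine replaces a lysine (n = 3). PARP1 is the ADP-ribose polymerase that binds DNA breaks, and EZH2 is the histone methyltransferase of the Polycomb repressive complex. The series concerns the methylation of PARP1 by EZH2, and the comparison asks how expression differs between cells that carry the lysine and cells that carry alanine in its place. The WT replicates 1, 2 and 3 held 19010927, 19048628 and 18984915 counts, and the K607A replicates 1, 2 and 3 held 18796167, 18914632 and 18977488. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Nor do the labels name a second stable line of either group, so a difference between lines cannot be told apart from the substitution.

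PARP1 itself was lower in the K607A cells. Its level was 2361 ± 86.1 CPM (counts scaled to the TMM library size; SD, n = 3) in WT and 1821 ± 43.3 CPM (SD, n = 3) in K607A, and each K607A library lay below each WT library. The log2 fold change was -0.37 with a standard error of 0.05 (edgeR quasi-likelihood, adjusted p = 0.00396). PARP1 lies on the minus strand of chromosome 1 from 226360210 to 226408154 (GRCh38), and its exonic counts do not separate transcripts of the construct from any that remained of the endogenous gene. EZH2, on chromosome 7 from 148807257 to 148884321, had 51.7 ± 2.84 CPM (SD, n = 3) in WT and 55.6 ± 0.188 in K607A, a difference that did not pass the test (log2 fold change 0.11, edgeR adjusted p = 0.423).

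**Figure D1:**
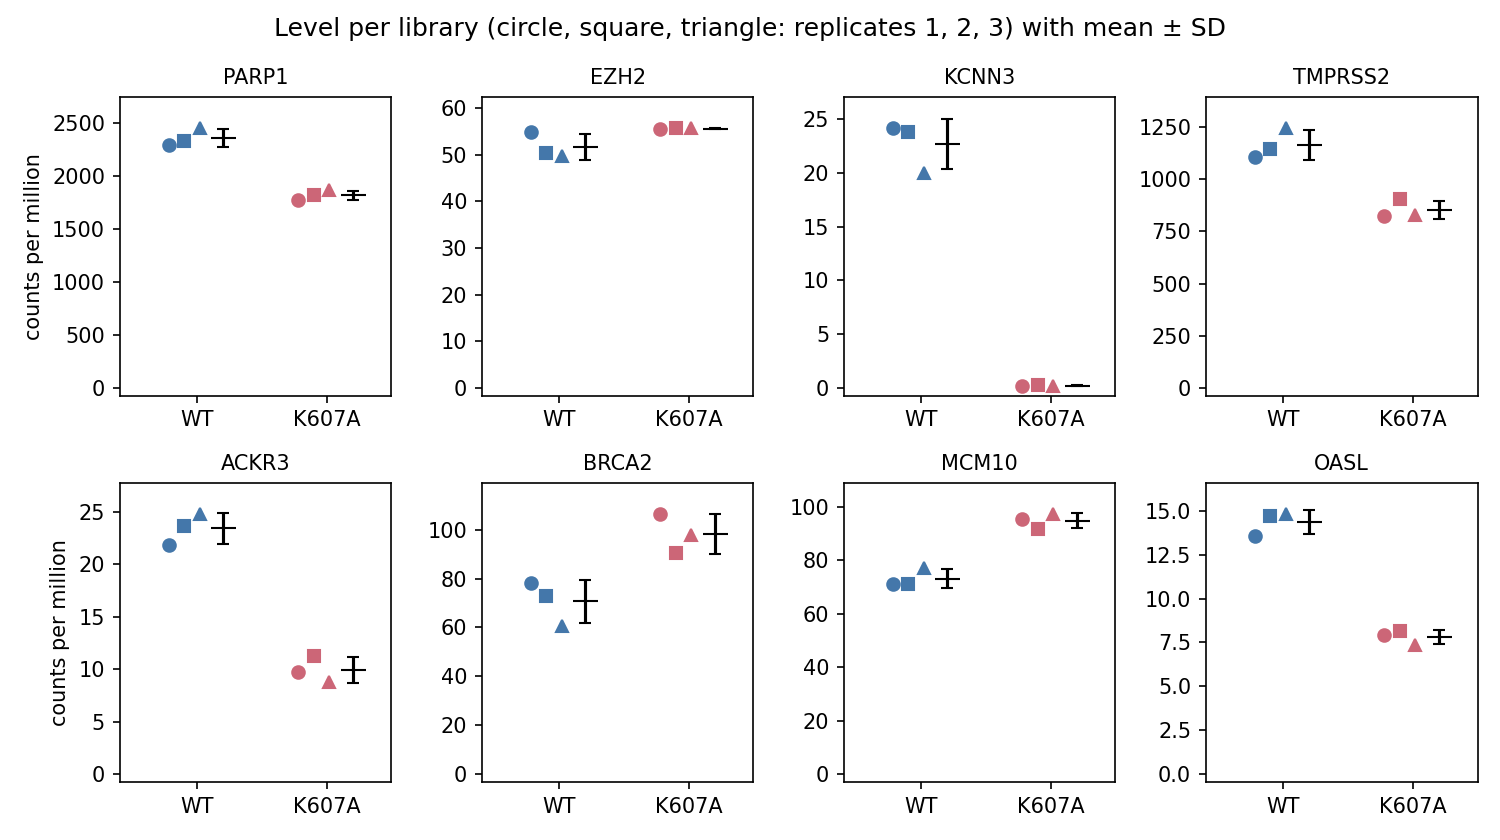
Level of 8 genes in CPM (vertical axis, from 0) in the 3 WT (blue) and 3 K607A (red) libraries, each marker a library, with the mean and SD in black beside each group. PARP1, TMPRSS2, KCNN3, ACKR3 and OASL were lower and BRCA2 and MCM10 higher in K607A, while EZH2 did not pass the test (51.7 against 55.6 CPM).

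The largest change was a near-loss of KCNN3, a small-conductance calcium-activated potassium channel on chromosome 1 from 154697455 to 154870281. It fell from 22.7 ± 2.33 CPM (SD, n = 3) in WT to 0.212 ± 0.0518 (SD, n = 3) in K607A, with a log2 fold change of -6.69 (standard error 0.19, edgeR adjusted p = 5.83e-11). Summed over each group it had 1294 counts in WT and 12 in K607A, which is 107-fold lower (95% Clopper-Pearson interval 60.9 to 207, counting error only). ACKR3, an atypical chemokine receptor, fell from 23.4 ± 1.49 to 9.91 ± 1.25 CPM (SD, n = 3), a log2 fold change of -1.24 (standard error 0.11, edgeR adjusted p = 8.09e-05). MAB21L4 fell by 1.32 on the log2 scale (standard error 0.12, adjusted p = 9.38e-05), the transcription cofactor LBH by 1.66 (0.17, adjusted p = 2.66e-04) and the semaphorin SEMA6B by 1.34 (0.16, adjusted p = 9.70e-04). The deiodinase DIO1, PHGR1, the olfactory receptor OR51E1 and the kallikrein KLK14 also fell, with log2 fold changes from -1.64 for DIO1 to -1.19 for KLK14. These genes were expressed at 3.21 to 4.05 CPM in WT. SMN1 (log2 fold change -3.72, standard error 0.46, adjusted p = 0.00106), CEP170 (-1.50, standard error 0.32, adjusted p = 0.0264) and KCNH6 (-1.26, standard error 0.26, adjusted p = 0.0221) completed the 12 genes with the largest decreases under the naming rule. HLA-B, given below, had a log2 fold change of -3.03 but was not picked by that rule, because its WT and K607A libraries overlapped. SMN1 has a near-identical copy, SMN2, and the sum of their counts did not pass the test (-1.18, standard error 0.45, adjusted p = 0.194). SMN1 had 272 counts in WT and 20 in K607A. SMN2 moved the other way, from 54 to 122, of which 95 came from K607A replicate 1. Over all alternatives the adjusted p of SMN1 ran from 4.27e-33 to 0.194. Of the 12 genes, 10 kept their calls whichever library was left out, CEP170 and KCNH6 being the exceptions. CEP170 missed the threshold without WT replicate 2 (adjusted p = 0.108), K607A replicate 1 (0.0769) or K607A replicate 3 (0.139), and ran from 2.75e-07 to 0.139 over its alternatives. It also missed it without both WT replicate 3 and K607A replicate 1 (0.107), the libraries at the ends of a trend with GC content. KCNH6 missed it without WT replicate 1 (0.0685), 2 (0.0511) or 3 (0.0562) and without K607A replicate 1 (0.0793), 2 (0.0503) or 3 (0.0967). Without both GC-end libraries its adjusted p was 0.112, and it ran from 0.0024 to 0.112.

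Among the genes higher in K607A, EXPH5, an effector of Rab GTPases, rose from 17.3 ± 1.44 to 25.3 ± 0.974 CPM (SD, n = 3), a log2 fold change of 0.55 (standard error 0.09, edgeR adjusted p = 0.00694). The inhibitor of differentiation genes ID1 and ID3 each rose by 0.79 on the log2 scale (standard error 0.13, adjusted p = 0.00788 and 0.00722), from 4.13 to 7.17 and from 11.2 to 19.4 CPM. The histone gene H2BC11, TEX15, the cilium kinesin KIF7 and the mitochondrial MT-ND2 and MT-ND1 were among the same 12 genes, with log2 fold changes from 0.54 to 0.71. Of the exonic bases of KIF7, 11.2% overlap TICRR. The 4 largest increases among the 12 genes picked by the naming rule were those of BDH1 (1.95, standard error 0.40, adjusted p = 0.0228), MOAP1 (1.88, 0.21, adjusted p = 6.74e-04), SDCCAG8 (1.58, 0.28, adjusted p = 0.0123) and INTS3 (1.39, 0.23, adjusted p = 0.00746). These 4 genes, ID3, SMN1 and CEP170 are also annotated on patches or alternate loci of the genome assembly. So were 7 of the 35 protein-coding genes that passed with an absolute log2 fold change of at least 1, against 362 of the 12533 protein-coding genes tested. MOAP1 and EXPH5 kept their calls whichever library was left out. Of the 12 genes, 2 passed without K607A replicate 3 (adjusted p of the others 0.0530 to 0.133), 6 without WT replicate 2, 7 without K607A replicate 1, 9 without WT replicate 3, and 11 each without WT replicate 1 and K607A replicate 2. BDH1 also missed the threshold with limma-voom (0.0949), and KIF7, MT-ND2 and MT-ND1 with DESeq2 (0.0540, 0.0984 and 0.110). Without both GC-end libraries H2BC11 (0.184), TEX15 (0.0868), KIF7 (0.103), MT-ND2 (0.121) and MT-ND1 (0.149) missed it. Over all alternatives of the 10 genes that lost a call the adjusted p ran from 7.66e-31 to 0.184.

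**Figure D2:**
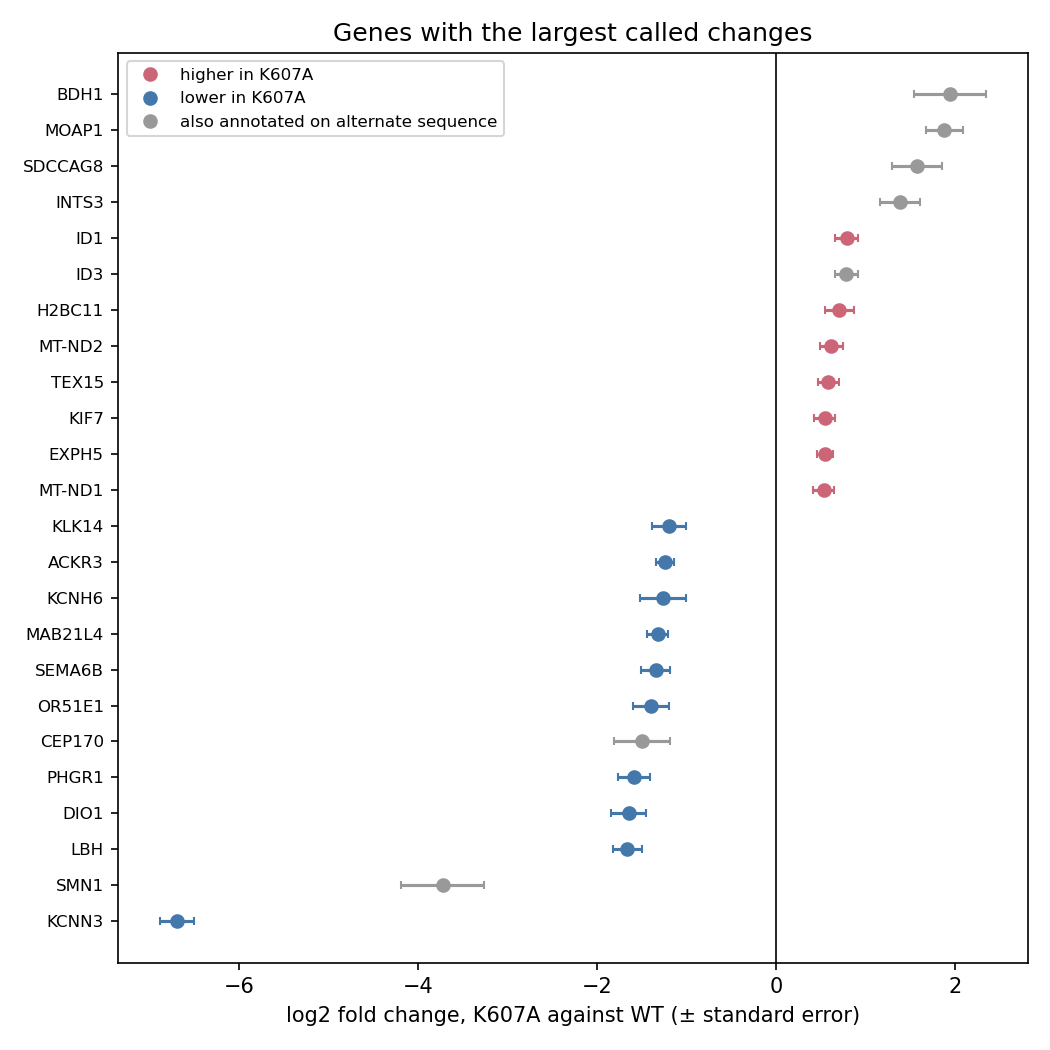
Log2 fold change (horizontal axis, K607A against WT, 3 libraries each) with its standard error for the 12 genes with the largest increases and the 12 with the largest decreases under the naming rule. That rule takes protein-coding genes past the threshold with at least 1 CPM and no overlap between groups. Genes also annotated on patches or alternate loci are grey. KCNN3 stands apart at -6.69, and the 4 largest increases shown, 1.39 to 1.95, are all grey.

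In total 310 of 15603 tested genes passed the threshold, 84 higher and 226 lower in K607A (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The median absolute log2 fold change of these 310 genes was 0.47, and 40 of them changed by at least 1 on the log2 scale, 9 higher and 31 lower. In 309 of the 310 the groups did not overlap, which follows largely from their selection by a test of the same difference. Genes lower in K607A made up 72.9% of the calls, 61.7% of 460 calls with DESeq2 and 55.4% of 1072 calls once each library's trend with GC content was removed. The number fell to 56 (10 higher, 46 lower) without K607A replicate 3, to 91 (14 higher, 77 lower) without WT replicate 2 and to 118 (30 higher, 88 lower) without K607A replicate 1, and rose to 450 (159 higher, 291 lower) without K607A replicate 2.

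Genes of DNA replication and the cell cycle were higher in the K607A cells. The 50 E2F target genes of DNA replication and the G1/S transition had a mean log2 fold change of 0.20 (standard error 0.01), 48 of them above 0. The standard error of a list mean, here and below, is taken over member genes and not over libraries. The replication initiation factor MCM10 rose from 73.2 ± 3.52 to 94.9 ± 2.91 CPM (SD, n = 3), a log2 fold change of 0.37 (standard error 0.06, edgeR adjusted p = 0.0084), and the ribonucleotide reductase subunit RRM2 rose by 0.30 (standard error 0.07, adjusted p = 0.0289). Over all genes 4 members passed by edgeR, 11 by DESeq2, 6 by limma-voom, 9 with the replicate number as a block, 28 once each library's GC trend was removed and 5 without both GC-end libraries, all higher. When adjusted over the list alone 31 passed by edgeR, also all higher. The list passed the camera test (adjusted p = 1.58e-14; adjusted p = 0.116 with an estimated correlation). Mitotic genes were higher by a mean of 0.16 (standard error 0.02) over 42 members (camera adjusted p = 8.47e-08; adjusted p = 0.127 with an estimated correlation). By edgeR the kinetochore protein CENPF alone rose over all genes (0.30, adjusted p = 0.0356), while 6 members rose with DESeq2, 1 with limma-voom, 4 with the replicate number as a block, 11 once the GC trend was removed and 3 without both GC-end libraries. When adjusted over the list alone 12 rose. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had a mean of 0.31 (standard error 0.11) over 22 members. They held only 0.0176% to 0.0235% of a library's counts, and members under 1 CPM weigh as much in that mean as the others. Of these H1-5 had a log2 fold change of 1.84 (0.193 CPM in WT, 0.708 in K607A) and H1-4 one of -0.75 (0.718 and 0.425). H2BC12 (0.45, adjusted p = 0.0152) was among 3 that rose over all genes (1 to 8 over 5 other fits), and 10 rose when adjusted over the list alone (camera adjusted p = 3.0e-05; adjusted p = 0.127 with an estimated correlation). Without K607A replicate 3 MCM10, RRM2, CENPF and H2BC12 missed the threshold (adjusted p = 0.0921, 0.139, 0.201 and 0.119), and likewise without WT replicate 2 (0.0674, 0.134, 0.120 and 0.0874). RRM2 and CENPF missed it without K607A replicate 1 (0.120 and 0.144) and CENPF without WT replicates 1 and 3 (0.0564 and 0.0558). Both missed it without both GC-end libraries (0.101 and 0.126), within 1.81e-05 to 0.201 over all alternatives of the 4 genes.

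The lists of homologous recombination and of end joining with DNA damage checkpoints were also higher. They passed camera with the preset correlation but not with an estimated one. The homologous recombination and Fanconi anaemia list, 45 genes, had a mean log2 fold change of 0.15 (standard error 0.02), with 39 members above 0. BRCA2 rose from 70.6 ± 8.95 to 98.2 ± 7.99 CPM (SD, n = 3), a log2 fold change of 0.48 (standard error 0.09, edgeR adjusted p = 0.0152). The recombination factor XRCC2 (0.42, adjusted p = 0.0197) and the nuclease-helicase DNA2 (0.38, adjusted p = 0.0192) rose with it. Over all genes 5 members rose (11 once the GC trend was removed, 1 without both GC-end libraries), and 9 rose when adjusted over the list alone (camera adjusted p = 3.82e-07; adjusted p = 0.139 with an estimated correlation). Among 35 genes of non-homologous end joining and DNA damage checkpoints the mean was also 0.15 (standard error 0.03; camera adjusted p = 3.0e-05; adjusted p = 0.127 with an estimated correlation). Of these 4 rose over all genes (2 to 7 over 5 other fits) and 12 when adjusted over the list alone, with the smallest p for the phosphatase CDC25A (0.36, adjusted p = 0.0138). Among end-joining genes PRKDC (0.21) passed over the list alone. XRCC5 (0.11), XRCC6 (0.04), XRCC4 (-0.07), LIG4 (0.11), NHEJ1 (0.08), DCLRE1C (0.24) and PAXX (0.21) did not, so a rise across these end-joining genes was not shown. In the same list RIF1 rose over all genes (0.37, edgeR adjusted p = 0.0238) and RNF168 (0.22) over the list alone, while TP53BP1 (0.01) and SHLD2 (0.15) passed in neither. RIF1 missed the threshold without WT replicate 2 (0.0793), K607A replicate 1 (0.0920) or K607A replicate 3 (0.133), and without both GC-end libraries. The median GC content was 43.1% for the homologous recombination list and 43.5% for mitosis. Log2 fold changes correlated with GC content at a Spearman rho of -0.28 across genes, which are not independent replicates. Without K607A replicate 3 BRCA2, XRCC2, DNA2 and CDC25A missed the threshold (adjusted p = 0.0818, 0.129, 0.107 and 0.111). XRCC2, DNA2 and CDC25A missed it without WT replicate 2 (0.0993, 0.0612 and 0.0648), and XRCC2 and DNA2 without K607A replicate 1 (0.0633 and 0.0588). Both missed it without both GC-end libraries (0.0827 and 0.0636), within 3.83e-08 to 0.129 over all alternatives of the 4 genes.

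**Figure D3:**
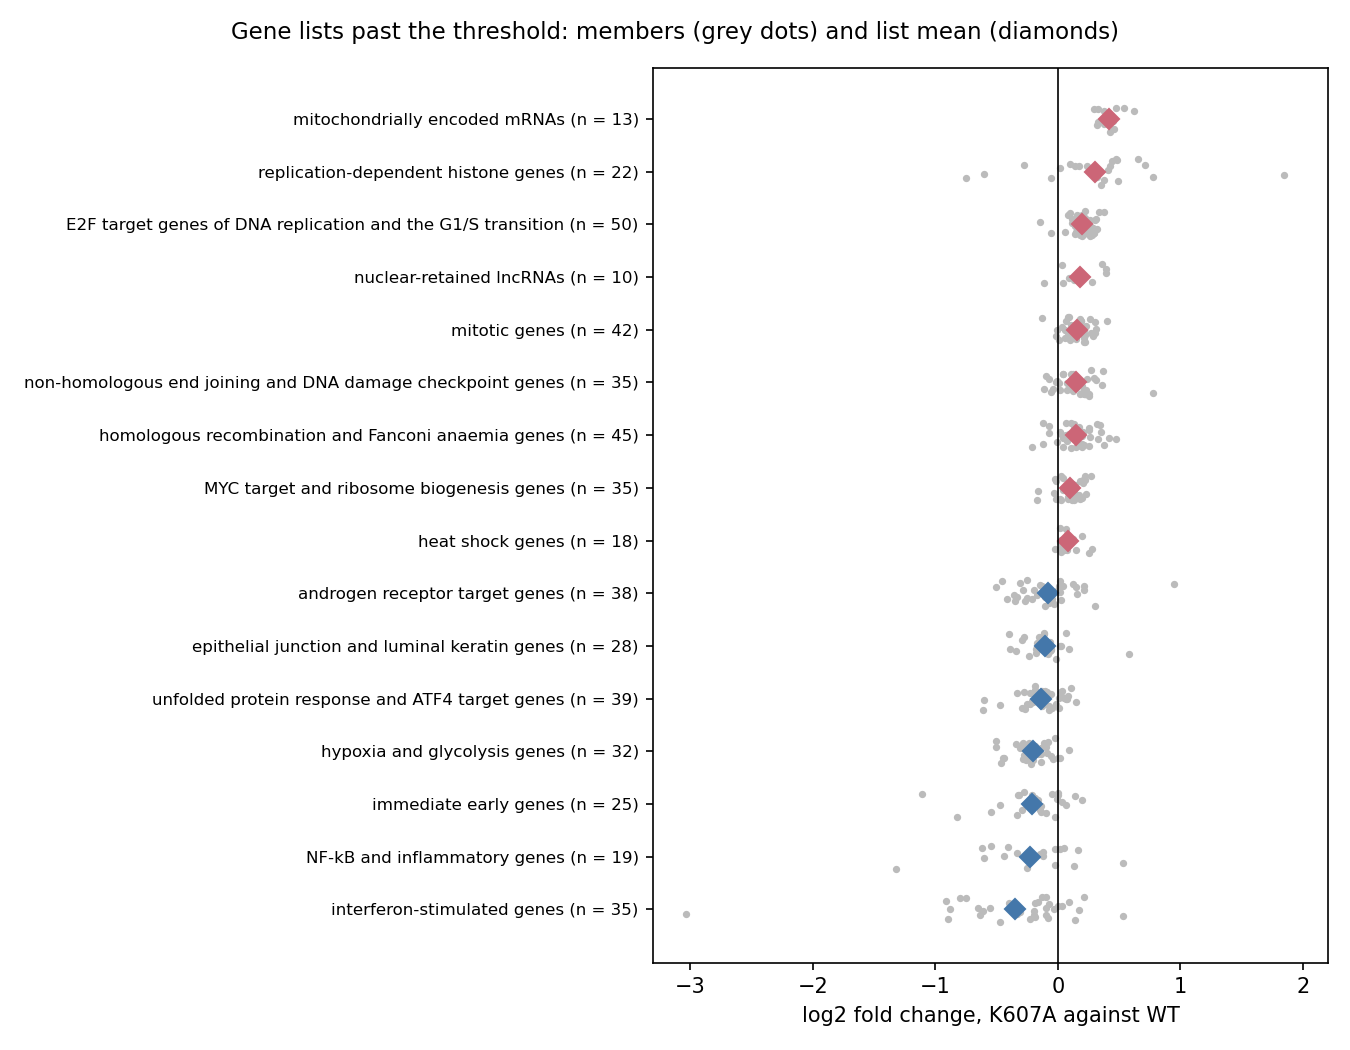
Log2 fold change (horizontal axis, K607A against WT, 3 libraries each) of every tested member (grey) of the 16 gene lists past the camera threshold with the preset correlation (0 with an estimated one), with each list's mean as a diamond, red where higher and blue where lower. Means run from -0.35 for interferon-stimulated genes to 0.41 for mitochondrially encoded mRNAs.

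The PARP family and base excision repair genes, 40 tested, did not move as a group. By edgeR only PARP1 passed over all genes and when adjusted over the list alone, while 3 members higher and 5 lower had an unadjusted p under 0.05. DESeq2 and limma-voom each called 1 member, lower, and edgeR after removal of the GC trend 1 higher and 1 lower, and the list did not pass (camera adjusted p = 0.854). Its median log2 fold change was 0.0039, its mean -0.012 (standard error 0.026) and the test pointed down. The flap endonuclease FEN1 had a log2 fold change of 0.20 (standard error 0.06, edgeR adjusted p = 0.118). Genes of NAD synthesis and consumption, NAD being the substrate of PARP1, did not pass either (20 genes, camera adjusted p = 0.845). Their median was 0.03, their mean -0.03 and the test pointed down. NMNAT2, which makes NAD, had the smallest p of that list (log2 fold change -0.30, standard error 0.09, adjusted p = 0.108). By edgeR 0 of its 20 members passed over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

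Polycomb components, 20 tested, did not pass as a list (mean log2 fold change 0.01, standard error 0.04, camera adjusted p = 0.854). Over all genes edgeR called 0 of them, 6 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, and 3 were lower once the GC trend was removed. When adjusted over the list alone 2 were higher and 3 lower, with log2 fold changes of -0.27 for JARID2 (adjusted p over all genes 0.0512), -0.41 for PHC1 (0.0643), -0.27 for CBX7 (0.0973) and 0.31 for EED (0.0745). Of 21 genes reported as silenced by EZH2 in prostate cancer, the metalloproteinase inhibitor TIMP2 fell from 116.3 ± 2.68 to 83.7 ± 7.44 CPM (SD, n = 3), a log2 fold change of -0.47 (standard error 0.07, edgeR adjusted p = 0.00396). The angiogenesis inhibitor VASH1, 21.8% of whose exonic bases overlap VASH1-AS1, fell by 0.77 (standard error 0.14, adjusted p = 0.012). Both also passed when adjusted over the list alone, and the list itself did not pass (median -0.02, mean -0.07, camera adjusted p = 0.432). VASH1 missed the threshold without WT replicate 2 (adjusted p = 0.0536) and without K607A replicate 3 (0.0762), within 1.77e-04 to 0.0762 over its alternatives.

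Androgen receptor target genes were lower on balance in K607A. The protease TMPRSS2 fell from 1166 ± 72.3 to 852 ± 44.3 CPM (SD, n = 3), a log2 fold change of -0.45 (standard error 0.06, edgeR adjusted p = 0.0033), and the channel TRPM8 from 214.6 ± 12.4 to 160.7 ± 2.37 (-0.42, standard error 0.06, adjusted p = 0.00406). NDRG1 fell by 0.51 (standard error 0.08, adjusted p = 0.00788) and TSC22D3 by 0.36 (standard error 0.06, adjusted p = 0.00875). Of 38 members 7 fell and 1 rose over all genes (5 to 10 and 0 to 1 over 5 other fits), and 9 fell and 1 rose when adjusted over the list alone, with a median of -0.08 and a mean of -0.08 (standard error 0.04; camera adjusted p = 0.00652; adjusted p = 0.176 with an estimated correlation). KLK3, which encodes prostate-specific antigen and was singled out after its values were seen, fell by 0.25 (standard error 0.06, adjusted p = 0.0394) from 4016 to 3367 CPM, and ELL2, also singled out afterwards, was the member that rose (0.30, standard error 0.06, adjusted p = 0.0212). Without K607A replicate 3, NDRG1, TSC22D3, KLK3 and ELL2 missed the threshold (adjusted p = 0.0523, 0.0958, 0.238 and 0.152). KLK3 and ELL2 also missed it without WT replicate 2 (0.129 and 0.0841) and K607A replicate 1 (0.186 and 0.0644), and KLK3 without WT replicate 3 (0.0529). Both missed it without both GC-end libraries (0.139 and 0.0523), within 8.8e-10 to 0.238 over the alternatives of the 4 genes.

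The list of epithelial junction and luminal keratin genes was lower as well, with a mean log2 fold change of -0.10 (standard error 0.03) over 28 genes and 23 below 0. Over all genes 4 fell (0 to 5 over 5 other fits), among them the transcription factor ELF3 (-0.40, edgeR adjusted p = 0.0228; 18.5% of its exonic bases overlap ELF3-AS1) and the claudin CLDN4 (-0.34, adjusted p = 0.0302). When adjusted over the list alone 6 fell, KRT8 among them, and 1 rose. The keratins KRT8 (-0.23, edgeR adjusted p = 0.0872), KRT18 (-0.01, 0.948) and KRT19 (-0.05, 0.872) did not pass over all genes. The list passed (camera adjusted p = 6.73e-04; adjusted p = 0.327 with an estimated correlation). It did not pass without both libraries at the ends of the GC trend, WT replicate 3 and K607A replicate 1 (mean -0.07, adjusted p = 0.0564, within 1.44e-04 to 0.0564 over its alternatives with the preset correlation). ELF3 and CLDN4 missed the threshold without WT replicate 2 (adjusted p = 0.0743 and 0.0695), K607A replicate 1 (0.111 and 0.118) or K607A replicate 3 (0.117 and 0.201), and without both GC-end libraries (0.104 and 0.110), within 2.49e-04 to 0.201 over their alternatives.

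Markers of other cell types and states were few and did not pass as lists. Of basal epithelial markers 8 were tested (mean -0.11, standard error 0.08, camera adjusted p = 0.238; 0.0408 with no filter on low counts, within 0.0408 to 0.571 with the preset correlation). Of endothelial markers 5 were tested (mean -0.12, standard error 0.12, camera adjusted p = 0.454) and of neuroendocrine markers 6 (mean -0.16, standard error 0.14, camera adjusted p = 0.499). By edgeR 0 members of these lists passed over all genes. An unadjusted p under 0.05 was reached by 0 basal, 1 endothelial and 3 neuroendocrine members, and DESeq2 called 1 neuroendocrine gene and limma-voom 0. Once the GC trend was removed 1 endothelial and 1 neuroendocrine member were lower, and 1 neuroendocrine member was with the replicate number as a block. When adjusted over the list alone, 0 basal, 1 endothelial and 1 neuroendocrine member fell. Fibroblast (4 tested) and leukocyte markers (3 tested) were too few for camera. FBN1, a fibrillin of the extracellular matrix, fell by 0.74 (standard error 0.18, edgeR adjusted p = 0.0491) from 3.22 to 1.93 CPM, also when adjusted over the list alone. It missed the threshold with DESeq2 (0.101) and limma-voom (0.0533), which called 0 fibroblast markers. It also missed it without WT replicate 1 (0.121), 2 (0.0966) or 3 (0.0799) and without K607A replicate 1 (0.172), 2 (0.0804) or 3 (0.0958), and without both GC-end libraries (0.162), within 0.0174 to 0.172 over its alternatives. The leukocyte markers LYZ, CSF1R and CORO1A had log2 fold changes of 0.18, 0.08 and 0.03. Of these edgeR called 0 of the 3 over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

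Interferon-stimulated genes were lower in K607A, with a mean log2 fold change of -0.35 (standard error 0.10), a median of -0.19 and 29 of 35 members below 0. OASL fell from 14.4 ± 0.693 to 7.81 ± 0.40 CPM (SD, n = 3; log2 fold change -0.88, standard error 0.10, edgeR adjusted p = 7.37e-04). The tetratricopeptide antiviral genes IFIT1 (-0.89, standard error 0.13, adjusted p = 0.00396), IFIT2 (-0.80, 0.10, adjusted p = 0.00198) and IFIT3 (-0.75, 0.14, adjusted p = 0.0158) fell with it. Over all genes 7 members fell (3 to 8 over 5 other fits), and 10 when adjusted over the list alone (camera adjusted p = 8.47e-08; adjusted p = 0.0753 with an estimated correlation, the smallest of any list). HLA-B, singled out after its values were seen and also annotated on alternate loci, had the largest fold change (-3.03, standard error 0.64, adjusted p = 0.0253). Its mean was 3.52 CPM in WT and 0.424 in K607A, but libraries of the groups overlapped. It pulls the list's mean further than the median. IFIT3 missed the threshold without WT replicate 2 (adjusted p = 0.0793) and K607A replicate 3 (0.0853), and without both GC-end libraries (0.0654), within 0.0018 to 0.0853 over its alternatives. HLA-B missed it without WT replicate 2 (0.0808) or 3 (0.0626) and without K607A replicate 1 (0.0683), 2 (0.0588) or 3 (0.118), with limma-voom (0.187) and without both GC-end libraries (0.151), within 2.29e-20 to 0.187.

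Hypoxia, unfolded protein response and immediate early genes were lower too. Hypoxia and glycolysis genes had a mean log2 fold change of -0.21 (standard error 0.03) over 32 genes, 29 of them below 0. The aldolase ALDOC fell by 0.50 (standard error 0.09, edgeR adjusted p = 0.0093) and the prolyl hydroxylase EGLN3 by 0.44 (standard error 0.08, adjusted p = 0.0139). Over all genes 4 fell (4 to 9 over 5 other fits) and 12 when adjusted over the list alone (camera adjusted p = 5.74e-07; adjusted p = 0.311 with an estimated correlation). Unfolded protein response and ATF4 target genes had a mean of -0.14 (standard error 0.03) over 39 genes, with 4 lower over all genes (2 to 9 over 5 other fits) and 10 when adjusted over the list alone (camera adjusted p = 3.0e-05; adjusted p = 0.0936 with an estimated correlation). They included the stress-induced regulators NUPR1 (-0.61, adjusted p = 0.0104) and DDIT4 (-0.47, adjusted p = 0.0165). ATF3 is counted both here and among the immediate early genes. Immediate early genes, which also respond to the handling of cells, had a mean of -0.21 (standard error 0.06) over 25 genes, with 2 lower over all genes (1 to 4 over 5 other fits) and 6 when adjusted over the list alone (camera adjusted p = 1.43e-04; adjusted p = 0.230 with an estimated correlation). Of these the MAP kinase phosphatase DUSP4 fell from 138 ± 2.26 to 94.8 ± 5.27 CPM (SD, n = 3), a log2 fold change of -0.54 (standard error 0.06, edgeR adjusted p = 7.37e-04). ALDOC and DUSP4 kept their calls whichever library was left out. EGLN3, NUPR1 and DDIT4 missed the threshold without K607A replicate 3 (adjusted p = 0.0677, 0.0556 and 0.119) and EGLN3 without K607A replicate 1 (0.0572) and without both GC-end libraries (0.0635), within 1.65e-12 to 0.119 over all alternatives of the 3 genes.

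NF-kB and inflammatory genes had a mean log2 fold change of -0.22 (standard error 0.09) over 19 genes, and the list passed (camera adjusted p = 0.00309; adjusted p = 0.127 with an estimated correlation). By edgeR 0 members passed over all genes, 8 had an unadjusted p under 0.05, all lower, and DESeq2 and limma-voom called 0. Over all genes 3 were lower once the GC trend was removed, 1 with the replicate number as a block and 1 without both libraries at the ends of that trend, and 4 were lower when adjusted over the list alone. The chemokine CCL20 had a log2 fold change of -0.54 (adjusted p = 0.0575) and complement C3 one of -1.32 (adjusted p = 0.0682). The list's mean was -0.14 with a filter at 1 CPM and -0.04 with no filter, and its adjusted p ran from 0.00182 to 0.0408 over its alternatives with the preset correlation.

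**Figure D4:**
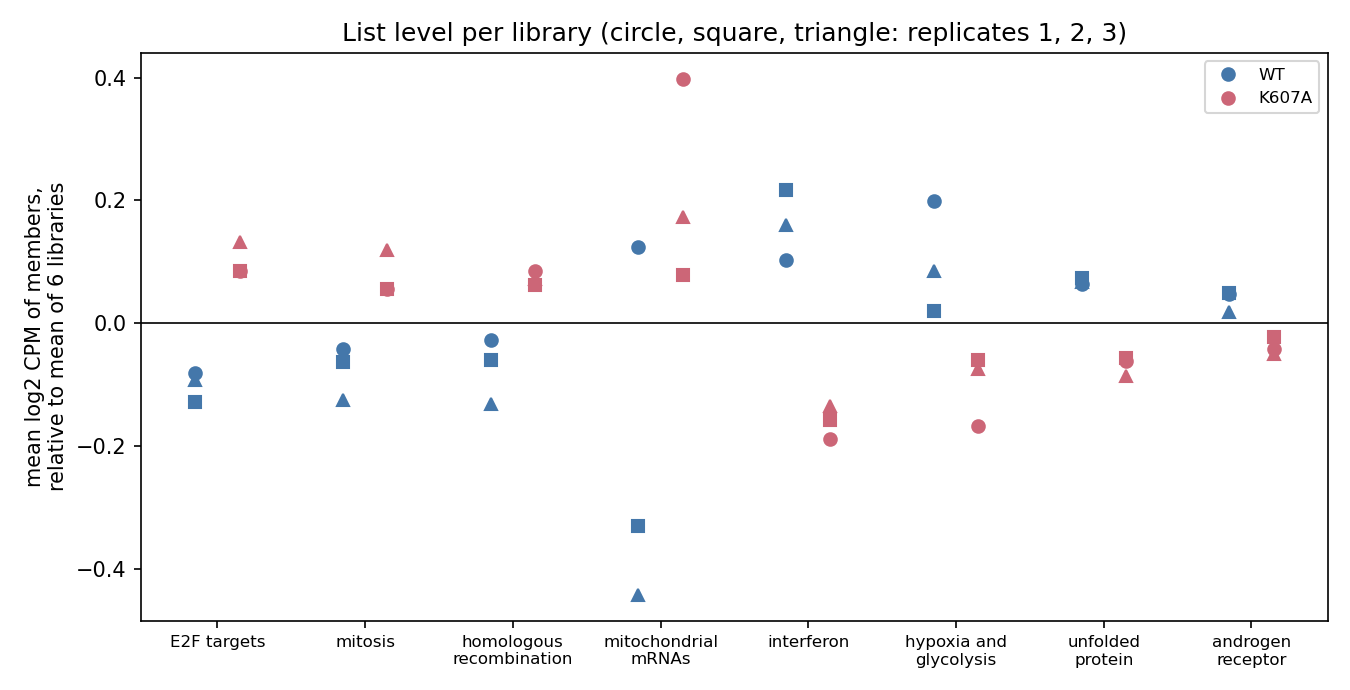
Mean log2 CPM of the members of 8 gene lists in each library, relative to the mean of the 6 libraries (vertical axis), with WT blue and K607A red. The groups separate in 7 lists and overlap in the mitochondrially encoded mRNAs, where WT replicate 1 (0.12) lies above K607A replicate 2 (0.08).

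Mitochondrially encoded mRNAs were higher in K607A as a list. All 13 had log2 fold changes above 0, with a mean of 0.41 (standard error over the 13 mRNAs 0.03). Relative to the mean of the 6 libraries, the list's mean log2 CPM was 0.12, -0.33 and -0.44 in WT replicates 1, 2 and 3. In K607A replicates 1, 2 and 3 it was 0.40, 0.08 and 0.17, so the groups overlapped. Mitochondrial transcripts made up 3.39%, 2.75% and 2.56% of the counts in WT replicates 1, 2 and 3 and 4.19%, 3.51% and 3.71% in K607A replicates 1, 2 and 3. Over all genes 4 rose, among them MT-ND2 (0.62, standard error 0.13, edgeR adjusted p = 0.0243) and MT-CO2 (0.33, standard error 0.07, adjusted p = 0.0289), and 11 rose when adjusted over the list alone. Over all genes 3 rose with DESeq2, 6 with limma-voom, 13 with the replicate number as a block, 9 once the GC trend was removed and 0 without both GC-end libraries. The list passed (camera adjusted p = 6.21e-07; adjusted p = 0.327 with an estimated correlation), and its mean was 0.21 without WT replicate 3 and K607A replicate 1. MT-ND2 and MT-CO2 missed the threshold without WT replicate 2 (adjusted p = 0.102 and 0.140), K607A replicate 1 (0.0765 and 0.125) or K607A replicate 3 (0.0967 and 0.129), and MT-ND2 without WT replicate 3 (0.0560) and with DESeq2 (0.0984). Both had 0.121 without both GC-end libraries, within 1.65e-12 to 0.140 over their alternatives.

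Nuclear-retained lncRNAs had a mean log2 fold change of 0.18 (standard error 0.05) over 10 genes and passed (camera adjusted p = 0.0269; adjusted p = 0.327 with an estimated correlation), with MALAT1 at 0.19 (standard error 0.11, edgeR adjusted p = 0.377). By edgeR 0 of the 10 passed over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The list missed the threshold once the GC trend was removed (mean 0.13, adjusted p = 0.0797), without WT replicate 3 (0.15, 0.0862), without K607A replicate 1 (0.12, 0.141), without both (0.09, 0.491) and with no filter (0.10, 0.0914), within 0.00952 to 0.491 over its alternatives with the preset correlation. Small structured RNAs had a mean of 0.13 (standard error 0.14) over 7 genes and did not pass (camera adjusted p = 0.0712). They passed without WT replicate 3 (mean 0.22, adjusted p = 0.0141), without K607A replicate 2 (0.27, 0.0179) and with a filter at 1 CPM (0.20, 0.0252), within 0.0141 to 0.132 over their alternatives with the preset correlation. The snoRNA host gene SNHG1 was the member that rose, over all genes and when adjusted over the list alone (0.35, standard error 0.07, edgeR adjusted p = 0.0154). It missed the threshold without WT replicate 2 (0.0686) and K607A replicate 3 (0.117), within 2.17e-04 to 0.117 over its alternatives. The trend with GC content differed between libraries within each group, with a Spearman rho across genes of 0.53 in WT replicate 3 and 0.33 in K607A replicate 2 but -0.48 in K607A replicate 1 and -0.32 in K607A replicate 3.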

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

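The GC correction, the fit without both libraries at the ends of the GC trend, the sum of SMN1 and SMN2 and the fit without genes on alternate loci were chosen only after the results were seen. PARP1 stayed lower under every alternative and past the threshold in all but that of an absolute log2 fold change of at least 1, with log2 fold changes of -0.40 to -0.35 when 1 library was left out. All 310 genes kept their direction wherever they were tested. The groups did not overlap in 309 of them, and every fit reused the same libraries. A kept direction, here and in the values below, was therefore largely fixed in advance and says little about robustness. Of 1104 alternative values of the 70 other genes picked by the naming rule and past the threshold, 913 stayed past it, 191 did not and 0 reversed; of 1114 values of picked genes not past it, 88 passed.

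The count rose from 310 to 804 (314 higher, 490 lower) with no filter, to 488 (163 higher) with the replicate number as a block, and to 1072 (478 higher, 594 lower) with the GC correction, in which 309 of the 310 genes stayed past the threshold; DESeq2 called 176 higher, and 135 were higher without genes on alternate loci. It fell to 40 (9 higher, 31 lower) with an absolute log2 fold change of at least 1, to 65 (12 higher, 53 lower) at an adjusted p under 0.01, and to 167 (105 lower) without both GC-end libraries, where 114 of the 310 genes stayed past the threshold. The stricter thresholds lower the count by construction; for the other alternatives the cause was not tested. With 1 library left out it ran from 56 to 450 (10 to 159 higher, 46 to 291 lower), and 21 of the 71 picked genes past the threshold, PARP1 included, stayed past it in each of these fits. No clear pairing by replicate number was seen. Correlations between same-number samples of the 2 groups, after removing each group's mean, were 0.09, -0.09 and 0.01. The samples numbered 1 correlated best with each other but not every sample did so with its own number, and a shared batch is not excluded.

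Of 29 lists 16 passed, and 14 to 18 did under the other settings. With an estimated correlation 0 passed in camera, 8 had an unadjusted p under 0.05, and fry called 11. In the simulated data a shifted list passed with an estimated correlation. Simulated genes were drawn independently, so that result does not show how the test performs on lists whose genes vary together. At 18796167 to 19048628 counts per library and 3 samples a group, changes near 1.3-fold were recovered in 41.2% of simulated genes. Real changes of that size, where present, could often go undetected in this design.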

Other observations

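The tests of the genes next to KCNN3, of the nuclear-encoded respiratory chain genes and of genes on alternate loci, and the fit without both libraries at the ends of the GC trend, were chosen only after the results were seen. The list of MYC target and ribosome biogenesis genes was higher in K607A, though MYC itself was not. Its mean log2 fold change was 0.10 (standard error 0.02) over 35 genes, with 29 above 0 (camera adjusted p = 3.87e-04, and 0.311 with an estimated correlation). By edgeR 0 of the 35 passed over all genes, 10 higher and 2 lower had an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. The 2 lower members were MYC (-0.16, edgeR unadjusted p = 0.0241) and ODC1 (-0.17, edgeR unadjusted p = 0.0110). With edgeR 9 were higher once the GC trend was removed and 4 without both libraries at its ends. When adjusted over the list alone 4 were higher; NIP7 had a log2 fold change of 0.27 (adjusted p = 0.0693). Heat shock genes had a mean of 0.08 (standard error 0.02) over 18 genes, 17 of them above 0 (camera adjusted p = 0.0269; adjusted p = 0.311 with an estimated correlation). By edgeR 0 passed over all genes, 4 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom 0 and edgeR after removal of the GC trend 2, and 3 were higher when adjusted over the list alone, HSPA4L having a log2 fold change of 0.26 (adjusted p = 0.0882). The list missed the threshold without WT replicate 1 (mean 0.06, adjusted p = 0.187), without K607A replicate 3 (0.06, 0.138) and with no filter (0.08, 0.0893), within 0.00429 to 0.187 over its alternatives with the preset correlation.

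Mesenchymal and extracellular matrix genes did not pass (20 genes, mean -0.14, standard error 0.09, camera adjusted p = 0.0673), although 2 fell over all genes (0 to 3 over 5 other fits) and 5 when adjusted over the list alone. The collagen COL5A1 fell by 0.67 (standard error 0.13, edgeR adjusted p = 0.019), but not past the threshold without WT replicate 2 (0.0663), K607A replicate 1 (0.0786) or K607A replicate 3 (0.0761) or without both GC-end libraries (0.0937), within 0.00252 to 0.0937 over its alternatives. The list passed without WT replicate 2 (mean -0.15, adjusted p = 0.0406), without K607A replicate 3 (-0.16, 0.037) and with a filter at 1 CPM (-0.16, 0.0362), within 0.0362 to 0.353 with the preset correlation. Cholesterol and fatty acid synthesis genes did not pass (33 genes, camera adjusted p = 0.454), their median being 0.05, their mean -0.0017 and the test pointing up. Over all genes and when adjusted over the list alone the regulator SREBF1 (-0.30, standard error 0.07, adjusted p = 0.0404) and the carboxylase ACACA (-0.90, standard error 0.15, adjusted p = 0.0084), which is also annotated on alternate loci, were lower. Without K607A replicate 3 both missed the threshold (0.224 and 0.0534), as did SREBF1 without WT replicates 1, 2 and 3 (0.0611, 0.0993 and 0.0636) and K607A replicate 1 (0.186) and without both GC-end libraries (0.155), within 1.18e-16 to 0.224 over their alternatives. The list of 31 p53 targets did not pass (mean 0.02, camera adjusted p = 0.504). CYFIP2 fell by 0.37 (standard error 0.07, adjusted p = 0.0154) over all genes (0 to 2 higher and 0 to 1 lower over 5 other fits), 1 member rose and 1 fell when adjusted over the list alone, and MDM2 had a log2 fold change of 0.35 (adjusted p = 0.0574). Cytoplasmic ribosomal protein genes did not pass (54 genes, mean -0.012, camera adjusted p = 0.767); RPS28, 20.6% of whose exonic bases overlap KANK3, rose by 0.35 (standard error 0.06, adjusted p = 0.0149), also when adjusted over the list alone. Without K607A replicate 3 CYFIP2 and RPS28 missed the threshold (both 0.119), as they did without WT replicate 2 (0.0579 and 0.0966) and K607A replicate 1 (0.0572 and 0.0586), and RPS28 without WT replicate 1 (0.0569) and CYFIP2 without both GC-end libraries (0.0585), within 1.2e-04 to 0.119 over their alternatives. Among nuclear-encoded respiratory chain genes (41 tested, median -0.03) edgeR called 0 over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

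The replication, mitosis and homologous recombination lists were higher in K607A, and a library bias with GC content could give such a pattern, since the latter pair hold AT-rich genes. After each library's GC trend was removed the means were 0.20 for E2F targets, 0.12 for mitosis, 0.11 for homologous recombination and 0.39 for mitochondrially encoded mRNAs, which argues against that bias as the whole cause. All 4 lists stayed past the camera threshold with the preset correlation, but 0 of them passed with an estimated one (adjusted p = 0.124, 0.151, 0.124 and 0.390), as was so before the correction. Without both libraries at the ends of the trend the E2F mean was 0.22, while that of the mitochondrially encoded mRNAs was 0.21, so the mitochondrial difference was smaller without those libraries. The lower PARP1 level of the K607A cells cannot be told apart from the substitution as a source of the E2F difference, because level and group coincide. The same holds for any other difference between the stable lines. Within the groups PARP1 and the E2F mean correlated over the 6 libraries with a Pearson r of 0.42 (exact permutation p = 0.472 over 36 within-group pairings) and a Spearman rho of 0.26 (exact permutation p = 0.722), and r was -0.61 without the 2 libraries farthest from the median. Nuclear-encoded respiratory chain genes had a mean of -0.0074 (41 genes, camera adjusted p = 0.632), so the mitochondrial difference was not shared with them. An effect of the K607A substitution stays open as an untested biological explanation, as does a difference between the stable lines.

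KCNN3 had 12 counts in the K607A libraries against 1294 in WT, and a deletion, a shift of reads to a paralog or a difference between the stable lines could each account for it. A deletion that reached its neighbours is argued against by the 10 nearest tested genes, whose median log2 fold change was -0.035. The summed level of KCNN1, KCNN2 and KCNN4 changed by -9.91 CPM while KCNN3 lost 22.5, so its reads did not move to these paralogs. A scan of 1935 windows of 50 neighbouring genes gave a largest absolute median of 0.09 (chromosome 19 from 1039997 to 2815807, permutation p = 0.047 over 1000 shuffled gene orders). That median lay just past the 95th percentile of the shuffles (0.0893 against 0.0892) but under the 0.2 set for a copy number difference. A median over 50 genes cannot show a gain or loss that covers only a few genes, so the scan does not address a small one at KCNN3. A deletion within KCNN3, silencing that arose in 1 stable line and an effect of the substitution remain open, and none of these was tested.

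Genes annotated on patches or alternate loci were frequent among the largest changes, with 7 of 35 protein-coding genes past the threshold at an absolute log2 fold change of at least 1. The odds ratio against the other tested protein-coding genes was 8.55 (95% interval 3.13 to 20.2, two-sided Fisher's exact p = 5.29e-05), and 10000 draws matched for expression gave a mean of 1.78 and at most 9 such genes (one-sided permutation p = 0.0016). Such genes had larger standard errors (median 0.13 against 0.08), but they were also expressed at lower levels (median 11.9 against 32.0 CPM), which by itself widens the error. A candidate explanation is that reads shared with the alternate copies made their counts unstable, which would concern BDH1, MOAP1, SDCCAG8, INTS3, CEP170, SMN1 and HLA-B. For MOAP1 such instability was not evident. It had 0.999 ± 0.281 CPM (SD, n = 3) in WT and 3.70 ± 0.319 in K607A, and kept its call whichever library was left out. How the authors' alignment treated alternate loci is not given in the sources used here, and a real change in any single one of these genes stays open.

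The real grouping gave 310 genes, and the highest count among the other splits of the 6 samples into 3 against 3 was 2; the real split is 1 of 10, too few for a share under 0.05.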
